A study of Homo sapiens with 24 samples.

How the data were processed

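The data were 24 ribosomal RNA depleted RNA sequencing libraries of cytoplasmic RNA from 293T cells, a human embryonic kidney line. Per the labels, DIS3 had been knocked down with a short hairpin RNA and restored as the wild-type protein (WT) or as the D146N mutant, and RNA came from fractions 3, 4, 7 and 8 of a sucrose density gradient. Each of the 8 groups of genotype and fraction held 3 replicates. Libraries of a genotype with the same replicate number were taken as a set of 4 fractions, although the labels do not say that they came from 1 gradient. The groups followed the sample titles and the column names, which matched for all 24 libraries.

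The deposited values were expected counts per gene in 61853 versioned Ensembl gene rows, not normalized by the authors. Of the nonzero values, 73.3% were whole within 0.005 and 97.0% lay within 0.01 of a multiple of one sixth, as when a read that fits several genes is shared out in parts. The submitters' processing notes name Bowtie2 2.3.5, HISAT2 2.1.0, SAMtools, featureCounts 1.5.1 and the genome build hg38, without the role or options of each. Before the data were examined, the groups, contrasts, tests, gene lists, alternatives and the rule for naming genes were fixed on the assumption of whole counts. Values were therefore rounded to whole numbers before fitting. Symbols were assigned to 99.92% of the rows. No row named a circular RNA, so circular RNA was not analysed here, and counts of a gene were never read as counts of its circular form. Positions and gene spans came from the RefSeq annotation of GRCh38.p14, the same build as hg38. The 46 chromosome Y copies of pseudoautosomal genes were left out of the gene lists and of the named genes.

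Library totals ran from 21.2 to 33.0 M counts. Values per gene are given as counts scaled to the library total (CPM) with the standard deviation (SD) of 3 libraries. Reads carried no molecular identifiers as far as the labels tell, so depth was taken as counting precision only. Fold changes came from edgeR 4.0.16 in R 4.3.3 with TMM normalization, filterByExpr by group, a robust quasi-likelihood fit of 8 group means to all 24 libraries, and Benjamini-Hochberg adjustment over the 18907 genes tested. A gene was called at an adjusted p under 0.05, and counts are also given for at least a 2-fold change. The biological coefficient of variation was 13.8%. TMM factors averaged 2.51 in WT fraction 3 and 0.365 in WT fraction 7, and 0.366 and 2.81 in the same fractions of D146N. A fold change is therefore relative to the typical gene and can differ in sign from the ratio of 2 CPM values. Library totals without factors were the named alternative.

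Contrasts were D146N against WT within each fraction, fractions 7 and 8 against 3 and 4 within each genotype (the mean of the log2 group means), the difference of these 2 contrasts (the interaction, D146N minus WT), a test of any genotype difference between the 4 fractions (the omnibus test), and fraction 4 against 3 and 8 against 7 over both genotypes. D146N was also compared with WT in sums of the 4 fractions of each set, 3 sums against 3, with 20562 genes tested. In that comparison each fraction weighed by its depth. The 32 gene lists, fixed by name or name pattern, were tested with camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with all other genes, whereas fry asks whether members move one way on balance. Class shares were compared by an exact two-sided permutation test on the logit share. Gene span, the genomic length from annotated start to end, was correlated with the fraction contrasts across the 16118 tested genes (85.2%) that had one; transcript lengths were not used.

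Named genes followed a fixed rule. DIS3 came first. Then came genes with an adjusted p under 0.05, a mean of at least 10 CPM after TMM, a symbol that is not a clone or contig name, and no overlap between the libraries of the 2 sides, ranked by the size of the log2 fold change. The rule took 12 each way for the WT fraction contrast and the summed contrast, 10 each way for the interaction, 6 each way within each fraction, and 5 each way for the remaining contrasts. Where genes are ranked by fold change below, the ranking is among genes that passed this rule. Up to 4 members with the smallest p of each called list were also eligible, with any member of the lists of exosome genes, exosome cofactors and nuclear RNAs. Other genes are named as chosen after their values were seen. The lists whose members are named were picked after the list results were seen. Rows with identical counts in every library (RPPH1 and ENSG00000259001, RN7SK and 7SK, RMRP and ENSG00000269900) are named once. Pseudogene rows such as RPL12P4 share reads with their parents and are not separate evidence.

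The tests were run on simulated data with 200 genes changed 1.5-, 2- or 4-fold, in 2 forms. The first form drew counts from fitted rates times effective library sizes and summed the simulated fractions. There, unchanged genes made up 5.4% of calls in D146N against WT in fraction 3, 4.4% in the WT fraction contrast, 15.5% in the interaction, 2.1% in fraction 4 against 3 and 94.5% (2844 of 3010) in the summed contrast. The second form, made after the first had been seen, scaled the simulated columns to the library totals and drew the sums from the rates of the sums; the tests themselves stayed as they were. It gave 5.6%, 3.0%, 5.1%, 5.5% and 4.5% in the same order. In the first form genes that were unchanged within each fraction were called in the sums, a limit of the summed contrast that the second form does not test. In the second form genes changed 2-fold were recovered at 53.8% in fraction 3, 68.3% in the WT fraction contrast, 40.3% in the interaction, 68.7% in fraction 4 against 3 and 67.7% in the sums.

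Alternatives were median-of-ratios size factors, library totals, no filter on low counts, DESeq2 1.42.0, leaving out each library or set, replicate number or set as a block, the 6 libraries of a contrast alone, small and mitochondrial RNAs left out, and, for the sums, the mean of the 4 within-fraction contrasts and limma voom with duplicateCorrelation by set. Chosen after seeing the data were leaving out also the rows that share counts with small RNAs, the totals of the remaining rows, sums of libraries thinned to the lowest total, and contrasts between groups of opposite fraction labels. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No library was left out of the comparisons as reported.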

Results

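RNA abundance was measured in 4 fractions of a sucrose density gradient, a tube in which particles such as ribosomes and other RNA and protein complexes separate by size and density. The cells were 293T with DIS3 knocked down and restored as WT or as D146N. DIS3 is the catalytic subunit of the RNA exosome, with a 3' to 5' exonuclease and an endonuclease centre, and D146N substitutes an aspartate of the endonuclease domain. The 8 groups (WT and D146N, fractions 3, 4, 7 and 8) held 3 libraries each. Library totals averaged 26.0 ± 1.12 M counts (SD, n = 3) in WT fraction 3, 21.8 ± 0.53 in WT fraction 4, 31.2 ± 0.91 in WT fraction 7 and 32.4 ± 0.90 in WT fraction 8. In D146N they averaged 26.0 ± 1.35, 26.1 ± 2.17, 21.8 ± 0.55 and 22.7 ± 0.29 in the same order. The 10 most abundant gene rows took 52.1% and 52.0% of counts in WT fractions 3 and 4 but 72.0% and 69.3% in WT fractions 7 and 8. In D146N they took 76.5% and 76.9% in fractions 3 and 4 and 48.8% and 49.9% in fractions 7 and 8. The labels do not say from which end the fractions were numbered or which particles each held. The study's title concerns circular RNA, whose rows the table did not name, so the comparisons are of genes.

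DIS3 (ENSG00000083520.15, hg38 chromosome 13, 72752169 to 72781900) was read at similar levels in both genotypes, but in opposite fractions. In WT it stood at 98.3 ± 12.0 CPM (SD, n = 3) in fraction 3, 95.1 ± 0.761 in fraction 4, 4.94 ± 0.362 in fraction 7 and 5.88 ± 0.403 in fraction 8. In D146N it stood at 8.58 ± 0.946, 9.12 ± 0.572, 101.0 ± 13.9 and 97.6 ± 4.99 CPM. Its log2 fold change in D146N against WT was -0.74 (SE 0.11, adjusted p 1.04e-06) in fraction 3, -0.60 (2.93e-05) in fraction 4, 1.41 (8.63e-13) in fraction 7 and 1.33 (2.27e-12) in fraction 8. In the summed fractions it did not pass (0.08, SE 0.05, adjusted p 0.285), although it passed on library totals (0.17), on totals without small and mitochondrial RNAs (0.25, chosen after seeing the data), as the mean of the 4 within-fraction contrasts (0.35) and with limma voom (0.36). Adjusted p over these 4 ran from 1.89e-05 to 0.00878. A gene count does not tell the endogenous transcript from the rescue construct, nor one allele from the other.

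The share of counts taken by each RNA class describes what each fraction held. RPPH1, the RNA of RNase P, which trims transfer RNA precursors, took 13% ± 0.755 of counts (SD, 6 libraries) in WT fractions 7 and 8 and 0.575% ± 0.0102 in WT fractions 3 and 4. In D146N it took 0.593% ± 0.0185 and 14.1% ± 0.221, the other way round. Cytosolic ribosomal protein mRNAs took 12.7% ± 0.670 in WT fractions 7 and 8 against 4.46% ± 0.0904 in fractions 3 and 4, and 4.29% ± 0.0859 against 9.58% ± 0.266 in D146N. Small nuclear RNAs, nearly all of them RN7SK, which restrains RNA polymerase II elongation, took 4.23% against 2% in WT and 2.08% against 7.12% in D146N. The class of 7SL, RNase P, RNase MRP, Y and vault RNAs took 41.0% against 34.3% in WT and 30.9% against 41.5% in D146N. Rows that share counts with small RNAs, such as those identical to RPPH1, RN7SK and RMRP, were counted in the library total but in no class. The shares of these RNAs and of their classes therefore leave those counts out. RPPH1 and its identical row each averaged 7.064% of counts over all libraries.

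Other classes ran the opposite way, oxidative phosphorylation mRNAs in D146N only. Small nucleolar and Cajal body RNAs took 0.365% in WT fractions 7 and 8 against 3.67% in fractions 3 and 4, and 4.33% against 0.393% in D146N. SCARNA2 alone made most of that (0.0934% against 2.53% in WT), whereas the median member of the class was higher in WT fractions 7 and 8 after TMM. Mitochondrially encoded RNAs took 0.970% ± 0.452 against 3.44% in WT and 3.75% against 1.10% in D146N, and histone mRNAs 1.56% against 2.29% and 3.33% against 0.843%. For these 2 classes too the direction of the share was opposite to that of the median member after TMM. Mitochondrially encoded mRNAs, however, took 0.959% against 3.41% in WT, nearly all of the mitochondrial share. The median of these mRNAs in WT ran the same way as the share. Proteasome mRNAs took 0.0299% against 0.142% in WT and 0.171% against 0.0257% in D146N, and mitochondrial ribosomal protein mRNAs 0.0928% against 0.155% and 0.190% against 0.0687%. WT fraction 8 replicate 3 raised some of these WT means. It held 0.0541% proteasome mRNAs, against 0.0252% and 0.0253% in replicates 1 and 2. For mitochondrially encoded RNAs it held 1.89%, against 0.829% and 0.821%. In WT the median mitochondrial ribosomal protein mRNA was again higher in fractions 7 and 8 after TMM (1.45). The median proteasome mRNA barely moved (0.09), and camera did not call that list. Oxidative phosphorylation mRNAs took 0.376% against 0.364% in WT and 0.465% against 0.259% in D146N. Each class named, in each fraction, gave an exact two-sided permutation p of 0.1 between genotypes, the smallest that 3 against 3 allows, so no share could reach 0.05.

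**Figure D1:**
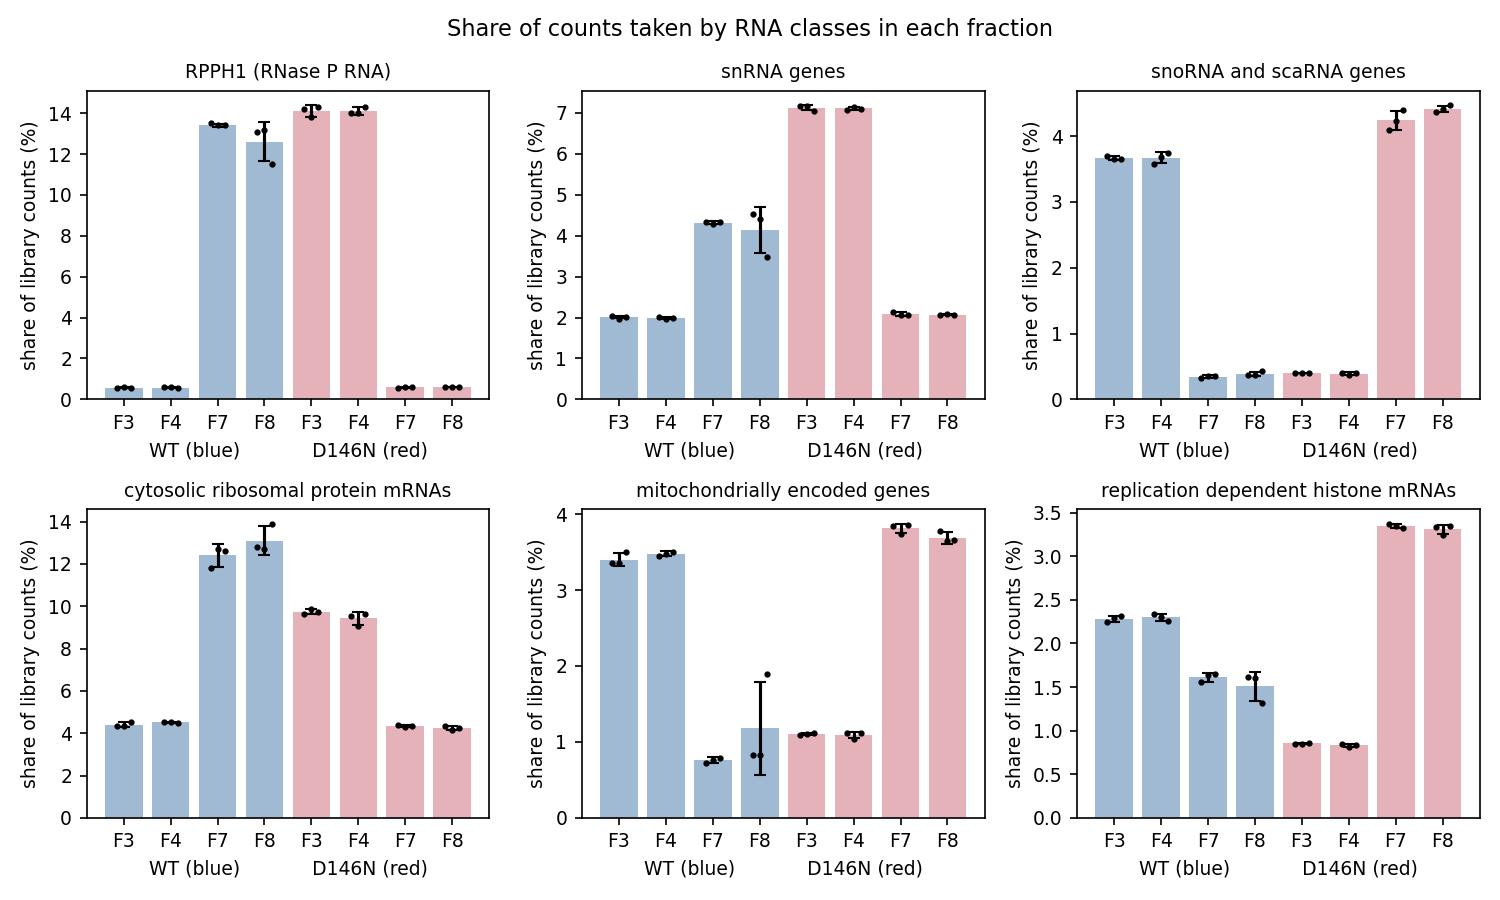
Share of library counts (percent, linear axis from 0) of 6 RNA classes in the 8 groups; bars are means, error bars the SD and dots the 3 libraries. Ribosomal protein mRNAs averaged 12.7% in WT fractions 7 and 8 and 9.58% in D146N fractions 3 and 4, above the other 4 groups.

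Fractions 7 and 8 against 3 and 4 within WT asked which RNAs were relatively enriched at which end of the sampled gradient. SCARNA16 (ENSG00000275143.1, chromosome 17, 77089307 to 77089493), a guide RNA for small nuclear RNA modification, rose from 0.683 ± 0.236 CPM (SD, n = 3) in fraction 3 to 119.1 ± 3.28 in fraction 7. RPPH1 (ENSG00000277209.1, chromosome 14, 20343071 to 20343411) rose from 5719 ± 141.0 to 134100 ± 701 CPM. RPLP1 (ENSG00000137818.12), a ribosomal stalk protein, rose from 1327 ± 33.6 to 9646 ± 467 CPM. DIAPH1 (ENSG00000131504.18, chromosome 5, 141515021 to 141619000), an actin nucleator, fell from 717 ± 28.9 to 8.32 ± 0.415 CPM, and AHNAK (ENSG00000124942.14), a giant scaffold protein, from 359 to 5.23 CPM.

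The genes that passed the naming rule are given here in order of their change on the TMM scale. SCARNA16 changed by a log2 fold of 9.80 (SE 0.20, adjusted p 4.4e-20), RPPH1 by 7.20 (0.12, 5.57e-33) and SNHG20, the noncoding host in which SCARNA16 lies, by 6.78 (0.14, 1.28e-22). SNHG20 had 133.9 CPM in WT fraction 7 where SCARNA16 had 119.1, so the host is not separate evidence. Next came a U2 small nuclear RNA copy at 5.94, with 50.5 ± 30.03 CPM in WT fraction 7, then SNORA53 at 5.83, RPLP1 at 5.52 (0.12, 1.39e-30), KRT10 at 5.51, RPL12P4 at 5.49, ZNF232-AS1 at 5.38, TP53TG1 at 5.37, RPL12P16 at 5.35 and BOLA3 at 5.34. Lowest among genes that passed the naming rule were ANAPC2, a subunit of the anaphase promoting complex, at -4.12 (0.09, 1.19e-29), DIAPH1 at -3.80 (0.08, 6.47e-31), the kinetochore protein CENPF at -3.80 (0.07, 1.07e-31), SPECC1 at -3.40, the nuclear pore protein TPR at -3.38, AHNAK at -3.36 (0.06, 3.79e-32), GOLGB1 at -3.16, AKAP12 at -3.09, PCLO at -3, REEP2 at -2.96, VCAN at -2.93 and CENPE at -2.89. The 12 higher genes kept their direction on library totals, which lower the typical gene, and in each of the 24 every library of one side lay above every library of the other. Among nuclear RNAs MALAT1 changed by -1.94 (0.07, 1.94e-24) and NEAT1 by -1.70, while PVT1 rose by 2.67, which became 0.01 on library totals.

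Of 18907 genes, 13980 were called, 6549 higher and 7431 lower, and 4957 and 3896 of these changed at least 2-fold. The 2 sides did not overlap in 10427 genes (55.1%), where chance gives 0.216% if the 6 libraries on each side were independent. They were 2 fractions of each of 3 sets. The balance of higher and lower turned with DESeq2 (6932 and 6844) and with median-of-ratios size factors (6881 and 6858). The median of all genes was -0.18 after TMM and -2.83 on library totals, which called 17255 genes with 8.4% of them higher, so the direction of a moderate change depends on the scaling.

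**Figure D2:**
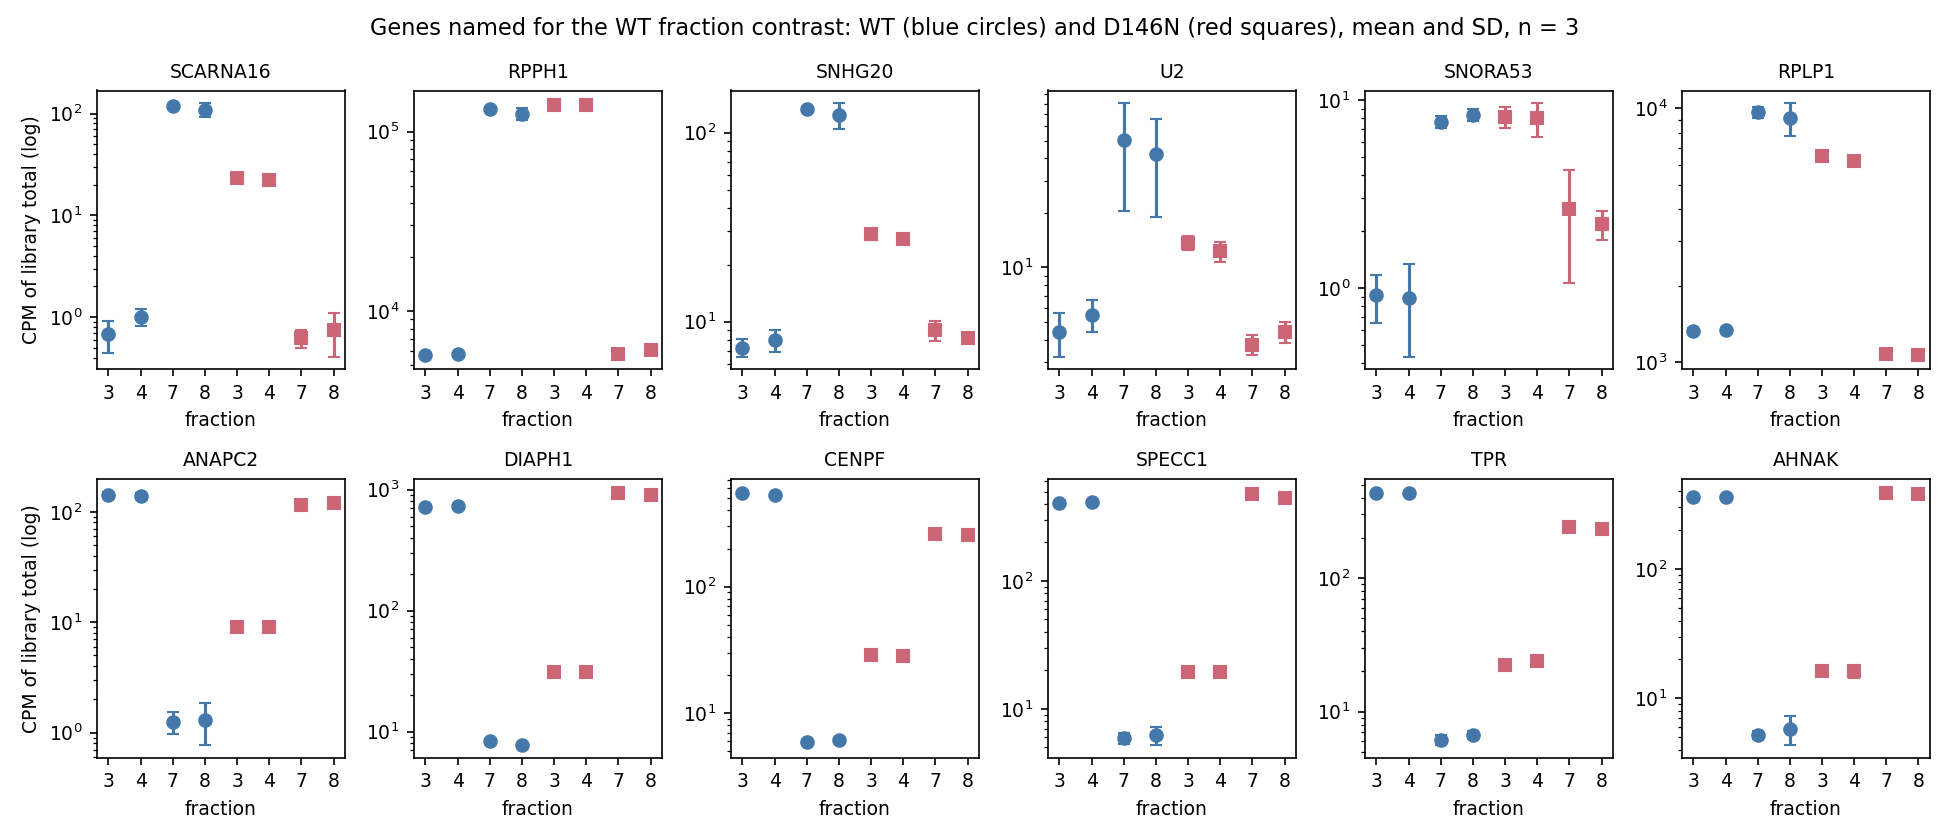
CPM of the library total (log axis) of 12 genes named in the WT fraction contrast, in the 8 groups; points are means of 3 libraries and error bars the SD. SCARNA16, RPPH1, SNHG20, U2, SNORA53 and RPLP1 stood higher in WT fractions 7 and 8 and D146N fractions 3 and 4, and ANAPC2, DIAPH1, CENPF, SPECC1, TPR and AHNAK in the other 4 groups; none changed direction between TMM and library totals.

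Of 85 cytosolic ribosomal protein mRNAs, 81 were higher in WT fractions 7 and 8, 3 lower and 1 did not pass (84 adjusted over the list alone), with a median log2 fold change of 4.01 and 1.31 on library totals; RPL29 stood at 4.59 and RPL9 at 4.01. Of 27 genes in the list of hosts of small nucleolar RNAs, mostly noncoding genes whose introns carry them, 24 were higher, 1 lower and 2 did not pass (25 adjusted over the list alone), with a median of 2.90 and 0.27 on library totals. The list also held SNORD3A, itself a small nucleolar RNA, and SNHG20, which is not separate evidence from SCARNA16. EPB41L4A-AS1 stood at 4.06, TAF1D at 3.95 and GAS5 at 3.86. Oxidative phosphorylation mRNAs had 82 of 95 members higher, 8 lower and 5 not passing (90 adjusted over the list alone), with ATP5PF at 4.27 and NDUFV2 at 3.60, but their median of 2.68 became -0.03 on library totals. Histone mRNAs had 58 of 63 higher, 1 lower and 4 not passing (59 adjusted over the list alone), with H3C6 at 3.19, but their median of 2.23 became -0.46 on library totals and the call was lost with an estimated correlation (adjusted p 0.109).

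Of 32 long giant mRNAs 29 were lower in WT fractions 7 and 8, 2 higher and 1 did not pass (31 adjusted over the list alone), with a median of -1.72 and SPTAN1 at -2.79. Of the 2 higher, NBEAL1, at 4.52, contains the pseudogene RPL12P16 in its span, and KMT2C, at 0.30 and named after its values were seen, became -2.39 on library totals and did not pass with no filter (0.13, adjusted p 0.107). S phase genes were lower in 21 of 22 and higher in 1 (22 adjusted over the list alone, median -1.04), with the replication factors FEN1 at -2.27, MCM7 at -1.80 and RRM1 at -1.76. G2/M genes were lower in 17 of 22 and higher in 5 (22 adjusted over the list alone, median -0.98), with MKI67 at -2.55 and TOP2A at -1.87, whereas UBE2C rose by 2.54 and stood at -0.11 on library totals. Integrated stress response genes were lower in 20 of 22, higher in 1 and not passing in 1 (21 adjusted over the list alone, median -0.59), with SLC7A5 at -1.60 and PHGDH at -1.54, whereas the stress factor DDIT3 rose by 2.32 and stood at -0.33 on library totals. Chaperones of the endoplasmic reticulum were lower in 17 of 23, higher in 3 and not passing in 3 (20 adjusted over the list alone, median -0.87), with HSPA5 at -1.88 and SEC61B at 3.06.

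Camera called 19 of the 32 lists in this contrast, from ribosomal protein mRNAs (adjusted p 2.78e-116) to cholesterol synthesis (0.0421). Called higher besides those above were mitochondrial ribosomal protein mRNAs (63 of 84 higher, 15 lower, 78 adjusted over the list alone, median 1.45), snRNA genes (43 of 57, 10, 53, 2.77), snoRNA and scaRNA genes (142 of 177, 7, 150, 2.53), host genes of well known circular RNAs (22 of 35, 9, 32, 0.81), the 7SL, RNase P, MRP, Y and vault RNAs (7 of 11, 4, 11, 1.99) and mitochondrially encoded genes (19 of 36, 12, 31, 0.53). On library totals the medians of these 6 lists were -1.23, 0.09, -0.16, -1.88, -0.71 and -2.09, so that only snRNA genes kept their sign, and with an estimated correlation snRNA genes (adjusted p 0.128), the 7SL class (0.294) and mitochondrially encoded genes (0.310) were lost. Called lower were glycolysis (0 of 17 higher, 15 lower, 15 adjusted over the list alone, median -1.07), heat shock chaperones (2 of 15, 11, 13, -1.10), fibroblast markers (0 of 10, 8, 9, -1.74) and cholesterol synthesis (2 of 22, 14, 16, -0.48). Of these, heat shock chaperones (adjusted p 0.171) and cholesterol synthesis (0.163) were lost with an estimated correlation, which left 13 of the 19 lists. Of the 13 lists not called, adjusted p was 0.172 for nuclear retained RNAs and for exosome cofactors, 0.181 for p53 targets, 0.207 for other RNA decay enzymes, 0.319 for immediate early genes, 0.454 for spliceosome and hnRNP mRNAs, 0.504 for epithelial markers, 0.706 for exosome subunits, 0.789 for translation factor TOP mRNAs, 0.816 for interferon stimulated genes, 0.835 for erythroid markers, 0.886 for proteasome mRNAs and 0.935 for mitochondrially encoded mRNAs. Median and mean differed in sign for spliceosome mRNAs (-0.32 and 0.16), TOP mRNAs (-0.28 and 0.26), mitochondrially encoded mRNAs (-0.40 and 0.07) and erythroid markers (0.11 and -0.17); the test ran against both for proteasome (0.09 and 0.20) and interferon genes (0.07 and 0.31).

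**Figure D3:**
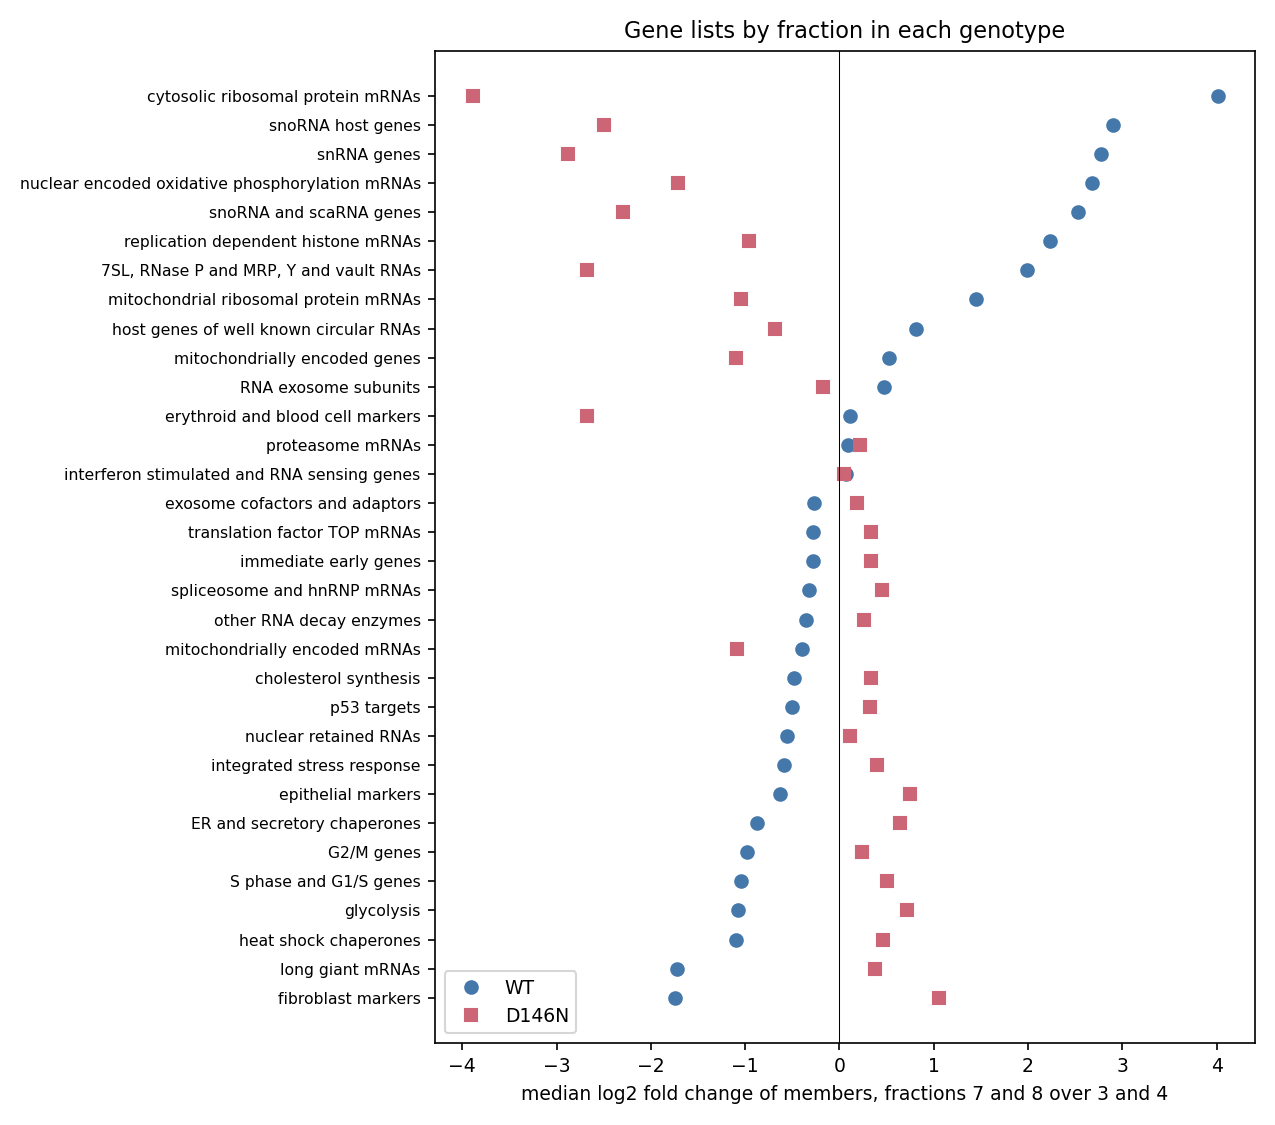
Median log2 fold change after TMM of fractions 7 and 8 against 3 and 4 for the gene lists, WT as circles and D146N as squares. Ribosomal protein mRNAs had 4.01 in WT and -3.89 in D146N; on library totals the WT medians of several lists above 0, such as histone mRNAs and oxidative phosphorylation, fell below 0.

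The same contrast within D146N ran the other way for 10491 of the 10561 genes called in both genotypes. DIAPH1 rose from 31.0 CPM in fraction 3 to 936 ± 26.9 (SD, n = 3) in fraction 7, AHNAK from 16.4 to 390 and ANAPC2 from 9.12 to 116. RPPH1 fell from 140900 ± 2918 to 5801 CPM, SCARNA16 from 23.4 ± 1.64 to 0.627 and RPLP1 from 6477 to 1083. The 5 largest log2 fold changes upward were DIAPH1 at 1.95 (SE 0.07, adjusted p 3.23e-23), SPECC1 at 1.65, AHNAK at 1.64, the kinase PRKCA at 1.64 and ALB at 1.61, and downward SCARNA16 at -7.96 (0.20), RPPH1 at -7.50 (0.13, 3.21e-33), SNORA23 at -6.29, RPL12P4 at -5.63 and RPL12P16 at -5.55. MALAT1 rose by 0.71 and NEAT1 by 0.85, while PVT1 changed by -2.31, which became 0.61 on library totals. Genes called numbered 11387, 5657 higher and 5730 lower, and 1064 and 4089 at least 2-fold. The 2 sides did not overlap in 8156 genes (43.1%, against 0.216% by chance if the 6 libraries on each side were independent). The balance was not stable. Without any 1 library of D146N fraction 7 or 8 the fit called 6857 to 6908 genes higher and 5210 to 5222 lower, with 1703 to 1762 higher at least 2-fold. With small and mitochondrial RNAs left out 6572 were higher and 5100 lower, and with the rows that share their counts also left out 5739 and 5637. The median of all genes was 0.10 after TMM and 3.00 on library totals, where 95.6% of 17572 calls were higher.

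Ribosomal protein mRNAs were lower in 82 of 85 and higher in 3 in D146N (85 adjusted over the list alone, median -3.89, and -0.96 on library totals). Hosts of small nucleolar RNAs were lower in 24 of 27 with 0 higher (24 adjusted over the list alone, median -2.50, and 0.43 on library totals). Oxidative phosphorylation mRNAs were lower in 80 of 95 and higher in 9 (89 adjusted over the list alone, median -1.71, and 1.20 on library totals). Long giant mRNAs were higher in 23 of 32, lower in 4 and not passing in 5 (27 adjusted over the list alone, median 0.38), and S phase genes in 17 of 22, lower in 1 and not passing in 4 (19 adjusted over the list alone, median 0.51). Camera called 18 lists and 13 with an estimated correlation; long giant mRNAs were then at 0.0570 and histone mRNAs at 0.336.

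**Figure D4:**
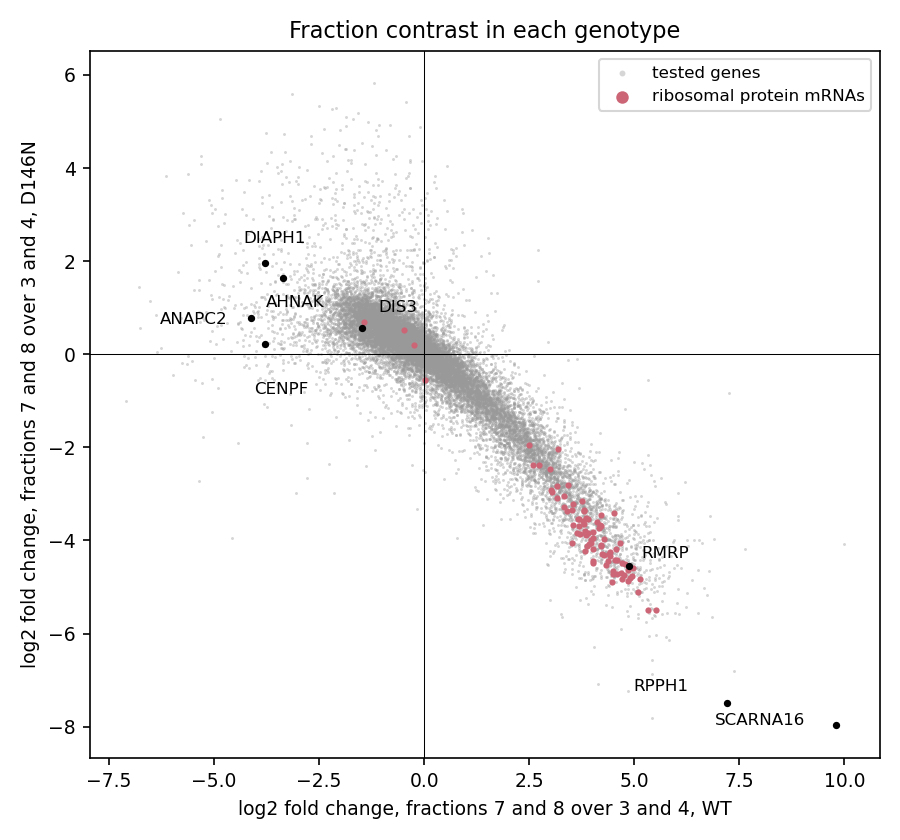
Log2 fold change after TMM of fractions 7 and 8 against 3 and 4 per gene, WT on the horizontal and D146N on the vertical axis; red points are ribosomal protein mRNAs. The genes fall along a descending line with a Pearson r of -0.880 across 18907 genes, which are not independent replicates.

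Within single fractions, D146N libraries were set against WT libraries of the same fraction label. A mutant effect and a difference in how the fractions of the genotypes were numbered give the same values here, so none of these changes can be assigned to D146N. In fraction 3 RPPH1 was 140900 ± 2918 CPM in D146N and 5719 ± 141.0 in WT (SD, n = 3), a log2 fold change of 7.40 (SE 0.18, adjusted p 6.02e-28). SCARNA16 differed by 7.87 (0.28, 1.83e-15), SNORA53 by 5.92, RPL12P4 by 5.38, RPL12 by 5.27 (0.13, 1.44e-27) and RPL12P16 by 5.27. The mitochondrial ribosomal RNAs MT-RNR1 (-5.77, SE 2.17, adjusted p 0.0359) and MT-RNR2 (-5.28, SE 1.62, 0.0120), targets of the ribosomal depletion, were lowest with large errors. The source of these errors was not tested. In WT fraction 8, whose libraries entered the same fit, MT-RNR1 stood at 0.191, 0.243 and 278 CPM in replicates 1, 2 and 3. MT-RNR1 no longer passed without WT fraction 3 replicate 2 (0.0557), without D146N fraction 3 replicate 1 (0.0940), 2 (0.0998) or 3 (0.0897), or with no filter (0.0561). Then came DIAPH1 at -1.75 (0.10, 4.1e-17), APOB at -1.68, AHNAK at -1.68 (0.08, 2.44e-19) and AFP at -1.66. In fraction 4 the highest were RPPH1 at 7.39, SCARNA16 at 7.23, SNORA53 at 5.94, SNORA23 at 5.47, RPL12P4 at 5.30 and RPL12P16 at 5.27, and the lowest DIAPH1 at -1.77, FN1 at -1.70, AHNAK at -1.69, AKAP12 at -1.64, SPECC1 at -1.63 and ALB at -1.62. Genes called numbered 9398 in fraction 3 (4877 higher and 4521 lower, 3806 and 1014 at least 2-fold) and 9163 in fraction 4 (4851 and 4312, 3803 and 985). The balance was not stable. Leaving out any 1 WT library of fraction 3 gave 4316 to 4354 higher and 5160 to 5338 lower there, with 1524 to 1655 lower at least 2-fold. Leaving out any 1 WT library of fraction 4 gave 4336 to 4405 higher and 5068 to 5106 lower, with 1550 to 1559 lower at least 2-fold. With small and mitochondrial RNAs left out lower genes again outnumbered higher ones, 5192 against 4396 and 4945 against 4401, as with no filter in fraction 3 (5186 against 5029). Leaving out also the rows that share their counts, chosen after seeing the data, gave more higher genes again, 4916 against 4394 and 4898 against 4155. No overlap was seen in 11274 (59.6%) and 10914 (57.7%) genes, where chance gives 10%. On library totals the median of all genes was -2.86 in both fractions, and 4.4% of 16746 and 4.3% of 16655 calls were higher.

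In fractions 7 and 8 the signs were reversed. DIAPH1 was 936 ± 26.9 CPM in D146N and 8.32 ± 0.415 in WT in fraction 7, a log2 fold change of 3.87 (SE 0.11, adjusted p 4.52e-26), followed by ANAPC2 at 3.59, SPECC1 at 3.39, AHNAK at 3.28, PRKCA at 2.94 and the adhesion and signalling protein CTNNB1 at 2.83. SCARNA16 was lowest at -10.49 (0.29, 2.39e-17), then RPPH1 at -7.48 (0.18, 2.9e-28), SNHG20 at -6.84, U2 at -6.69, RPLP1 at -6.10 and RPL12P4 at -5.84. Fraction 8 gave DIAPH1 at 4.12 (0.11, 1.18e-26), ANAPC2 at 3.85, SPECC1 at 3.45, AHNAK at 3.36, PRKCA at 3.11 and AKAP12 at 2.99, and SCARNA16 at -9.94, RPPH1 at -7.12, SNHG20 at -6.69, U2 at -6.03, RPLP1 at -5.85 and RPL12P4 at -5.73. Calls numbered 12000 in fraction 7 (6126 higher and 5874 lower, 3335 and 4714 at least 2-fold) and 12314 in fraction 8 (6154 and 6160, 3287 and 4914). Here too the balance turned, in fraction 7 without WT replicate 1 (5657 higher and 5670 lower) or 2 (5569 and 5586), with DESeq2 (5549 and 6265) and with median-of-ratios size factors (5618 and 6179). In fraction 8 it turned without WT replicate 3 (5930 and 5818), without any 1 D146N library (6521 to 6579 and 5642 to 5671), with no filter (6856 and 6557), with small and mitochondrial RNAs left out (6482 and 5665) and with the 6 libraries compared alone (5882 and 5204). It did not turn when the rows that share counts with small RNAs were also left out (5948 and 6225). No overlap was seen in 13384 (70.8%) and 12871 (68.1%) genes, against 10% by chance. On library totals the median of all genes was 3.09 in fraction 7 and 2.78 in fraction 8, and 93.9% of 16821 and 93.0% of 16446 calls were higher. On library totals the genes named as higher in fractions 3 and 4 and as lower in fractions 7 and 8 kept their direction against that shift.

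Ribosomal protein mRNAs were higher in D146N in 81 of 85 members in fraction 3, lower in 3 and not passing in 1 (84 adjusted over the list alone, median 3.75, and 0.97 on library totals), and lower in 81 and higher in 3 in fraction 7 (84 adjusted over the list alone, median -4.23, and -1.28 on library totals). Long giant mRNAs were lower in 29 of 32 in fraction 3, higher in 1 and not passing in 2 (30 adjusted over the list alone, median -0.98), and higher in 27 and lower in 4 in fraction 7 (31 adjusted over the list alone, median 1.25). Hosts of small nucleolar RNAs were higher in 26 of 27 and lower in 1 in fraction 3 (27 adjusted over the list alone, median 2.69, which became -0.09 on library totals). Camera called 20, 20, 19 and 18 lists in fractions 3, 4, 7 and 8, and 12, 13, 14 and 13 with an estimated correlation.

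The interaction set the fraction contrasts of the genotypes against each other with the fractions as labelled, under the same limit on numbering. SCARNA16 differed most (D146N minus WT -17.76), then RPPH1 (-14.70, SE 0.18, adjusted p 3.4e-38), SNHG20, RPL12P4, RPLP1, RPL12P16, RPL12, U2, SNORA53 and SNORA23, which ran from -11.43 to -10.32. In the other direction DIAPH1 differed by 5.75 (0.11, 6.17e-33), and SPECC1, AHNAK, ANAPC2, AKAP12, PRKCA, the cytoskeletal linker MACF1, CTNNB1, MT-RNR2 and DAAM1 by 5.05 to 4.10. MT-RNR2, at 4.12, had an SE of 1.26. DIS3 differed by 2.04 (0.11, 5.88e-18), MALAT1 by 2.66 and NEAT1 by 2.54, and PVT1 by -4.98, which became 0.61 on library totals. The list of exosome subunits also held the associated factors C1D and MPHOSPH6. Of its 14 genes 5 were higher, 8 lower and 1 did not pass (13 adjusted over the list alone), while on library totals all 14 were above 0, and camera did not call the list (adjusted p 0.692). EXOSC9 differed by 1.96, EXOSC6 by 1.87, DIS3L by 1.42 and EXOSC10 by 0.92. EXOSC1 differed by -4.24, C1D by -3.60, EXOSC8 by -2.67 and EXOSC4 by -2.48, which became 1.34, 1.97, 2.93 and 3.10 on library totals. Calls numbered 14574 of 18907 genes, 7883 higher and 6691 lower (6097 and 5848 at least 2-fold), and the sets of the 2 genotypes did not overlap in 15072 (79.7%, against 10% by chance). The median of all genes was 0.33 after TMM and 5.88 on library totals. The omnibus test called 13520 genes. Of 10561 genes called in the fraction contrast of both genotypes, 10491 (99.3%) had opposite signs and 70 the same sign. Across genes, which are not independent replicates, the 2 contrasts had a Pearson r of -0.880 and a Spearman rho of -0.862, and an r of -0.957 over 3963 genes of at least 10 CPM. Ribosomal protein mRNAs were lower in 81 of 85, higher in 3 and not passing in 1 (84 adjusted over the list alone, median -7.91, and -2.28 on library totals) and long giant mRNAs higher in 29 of 32 and lower in 3 (32 adjusted over the list alone, median 2.22). Camera called 19 lists, 13 with an estimated correlation.

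The sums of 4 fractions per set compared the genotypes over the sampled fractions together. Each fraction weighed by its sequencing depth, which differed between the genotypes, so the sums were not free of the fraction profile. Among genes that passed the naming rule, SCARNA16 (log2 fold change -2.48, SE 0.08, adjusted p 1.9e-08) and its host SNHG20 (-2.10, 0.07, 4.02e-08), which is not separate evidence, were lowest in D146N. U2 followed at -1.76 (0.31, 0.0192), a call that leaving out any of 5 of the 6 sets ended (all but WT replicate 2, adjusted p 0.0574 to 0.0814). Then came COPB2-DT at -1.14, ZNF232-AS1 at -1.12, SNORA12 at -1.12 (0.04, 3.59e-12), the ribosome assembly factor RRP12 at -1.07, RPL39P3 at -1.04, RPL39 at -1.04 (0.07, 6.79e-06), and the spliceosomal RNAs RNU4-2 at -1, RNU12 at -0.96 and RNU5F-1 at -0.96. Among the highest were MTATP6P1, a nuclear copy of mitochondrial sequence, at 0.83 (0.05, 2.07e-07), SNORA23 at 0.80, MT-ND6 at 0.71, MT-ND5 at 0.60 (0.04, 8.83e-09), PRRC2A at 0.60 (2.42e-09), HNRNPA1P10 at 0.55, the kinase chaperone CDC37 at 0.54, FOXRED2 at 0.53, SNRNP70 at 0.53, ZNF503 at 0.52 and RN7SKP80 at 0.52. These genes kept their direction on library totals. SNORA23 did not pass as the mean of the 4 within-fraction contrasts (0.20, adjusted p 0.388) or with limma voom (0.24, 0.349), while it passed in the other alternatives. Of the 14 genes in the list of exosome subunits 4 were higher, 0 lower and 10 did not pass (7 adjusted over the list alone). Of 17 exosome cofactors 5 were higher, 3 lower and 9 did not pass (12 adjusted over the list alone), and camera called neither list (adjusted p 0.202 and 0.677). Of these 12 genes only the subunit EXOSC6 (0.17) and the cofactor SRRT (0.41) passed in every alternative.

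Ribosomal protein mRNAs were lower in the D146N sums in 67 of 85 members, higher in 1 and not passing in 17 (71 adjusted over the list alone, median -0.40), with RPS14 at -0.80 and RPL37A at -0.75, a call lost with an estimated correlation (adjusted p 0.0549). Small nuclear RNAs were lower in 39 of 57, higher in 1 and not passing in 17 (45 adjusted over the list alone, median -0.70), and small nucleolar and Cajal body RNAs in 74, higher in 4 and not passing in 98 (84 adjusted over the list alone, median -0.52). Long giant mRNAs were lower in 22 of 32 and higher in 5 (27 adjusted over the list alone, median -0.34), also lost with an estimated correlation (0.0603). Their members CENPF (-0.91), AKAP9 (-0.90) and GOLGB1 (-0.76) reversed to 0.57, 0.17 and 0.36 as the mean of the 4 within-fraction contrasts (adjusted p 5.61e-11, 0.0176 and 2.42e-06) and to 0.57, 0.18 and 0.37 with limma voom, so no direction is claimed for them. Host genes of well known circular RNAs were lower in 22 of 35, higher in 0 and not passing in 13 (24 adjusted over the list alone, median -0.24), with RNF13 at -0.57 and BIRC6 at -0.54. Chaperones of the endoplasmic reticulum were higher in 15 of 23 and lower in 1 (17 adjusted over the list alone, median 0.25), with PDIA6 at 0.45 and HYOU1 at 0.33. In the mitochondrially encoded list the transfer RNAs MT-TW (-4.87) and MT-TT (-2.02) were lower while 7 of 13 mRNAs were higher and 2 lower (9 adjusted over the list alone, median 0.27), a call lost with an estimated correlation (0.377). Camera called 17 lists and 5 with an estimated correlation, namely small nuclear RNAs (0.0498), snoRNA and scaRNA genes (0.0171), snoRNA hosts (0.0498), circular RNA host genes (0.0385) and endoplasmic reticulum chaperones (0.0498). The lists were not tested in sums of thinned libraries. These calls cannot be told apart from the part of the fraction profile that the sums carried.

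The sums called 5636 of 20562 genes, 3071 higher and 2565 lower, but only 44 and 256 at least 2-fold. DESeq2 called 5180 (31 and 230 at least 2-fold), limma voom 3663 (65 and 92) and the mean of the 4 contrasts 4377 (62 and 81), so the 2-fold excess of lower genes depended on the method. The 2 genotypes did not overlap in 8570 genes (41.7%, against 10% by chance). The median of all genes was 0.01 after TMM and 0.10 on library totals, where 74.8% of 6322 calls were higher. The sums carried part of the fraction profile, with an r across genes, which are not independent replicates, of -0.379 with the WT fraction contrast and 0.509 with the D146N one. Sums of libraries thinned to one depth, chosen after seeing the data, called 4924 genes (2641 higher and 2283 lower) with an r of 0.982 to the fold changes of the full sums. The thinned sums still had an r of -0.266 with the WT fraction contrast. In simulation, genes unchanged within every fraction made up 94.5% of summed calls when simulated fractions were summed (first form), and unchanged genes made up 4.5% when the sums were drawn directly (second form, made after the first was seen). A small summed change is therefore weak evidence of a change within any fraction.

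Fraction 4 against 3 over both genotypes gave 0 calls with edgeR (830 genes at an unadjusted p under 0.05) and 0 with DESeq2. Fraction 8 against 7 gave 0 calls (1215 at an unadjusted p under 0.05), while the fit with no filter called 26 (24 higher and 2 lower), DESeq2 called 1, ENSG00000288707, and the fit without D146N fraction 7 replicate 1 called ENSG00000288707 and ABCA15P, named after their values were seen. In the second form of simulation the same test recovered 68.7% of genes changed 2-fold between fractions 4 and 3, in the same direction in both genotypes. A step between adjacent fractions that ran in opposite directions in the genotypes would cancel in these contrasts. The 0 calls therefore do not show that adjacent fractions were alike within a genotype. Camera called 0 lists for 4 against 3 (0 with an estimated correlation and 0 by fry) and 7 for 8 against 7 (0 and 0). Library pairs from adjacent fractions of a genotype differed by a chi-square per degree of freedom of 1.95 to 5.71 (median 4.34), and replicates of the same group by 1.75 to 5.49 (median 4.27), leaving out WT fraction 8 replicate 3. No pair was within counting noise, so no libraries were merged. That replicate stood apart from the other WT libraries of fractions 7 and 8 (median rank correlation 0.924, against 0.979 among the others), with RPLP0 at 3940 CPM against 549 and 544 in replicates 1 and 2. Without it the fraction 8 comparison called 11748 genes in place of 12314, and without WT fraction 8 replicate 1 or 2 it called 11922 or 11884. The genes RPLP0, RACK1, GAPDH and SRM, given where that library is discussed, were chosen after their values were seen.

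Gene span was related to the fraction contrasts in opposite directions in the 2 genotypes. Across 16118 genes, which are not independent replicates, log2 gene span had a Spearman rho of -0.143 (Pearson r -0.232) with the WT contrast and 0.108 (0.258) with the D146N contrast. At 10 CPM or more (3813 genes) the rho was -0.331 (-0.442) and 0.253 (0.440). The 3 sets gave -0.125, -0.125 and -0.177 in WT and 0.098, 0.125 and 0.106 in D146N. In 5 equal groups by span, the shortest genes (median 2.63 kb) had a median log2 fold change of 0.74 in WT and -0.52 in D146N, and the other groups, with medians of 11.6, 26.8, 56.3 and 155.0 kb, had -0.28, -0.44, -0.36 and -0.22 in WT and 0.22, 0.28, 0.22 and 0.07 in D146N. The shortest genes stood apart from the others, among which the medians did not move in 1 direction with span. In 5 groups of the genes of at least 10 CPM, a grouping chosen after seeing the data, the medians from the shortest to the longest were 2.58, 0, -0.55, -0.51 and -0.24 in WT and -1.95, 0.07, 0.33, 0.23 and -0.01 in D146N. Gene span includes introns and is not transcript length.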

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

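Of the tests that weigh explanations here, those of an exchange of fractions, of scaling, of movement by D146N, of carry-over and of depth were chosen after the result was seen, and the counts over regroupings of the libraries were chosen before.

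With the fractions as labelled, the contrast of fractions 7 and 8 with 3 and 4 differed between the genotypes for 14574 genes by the interaction and 13520 by the omnibus test, and for 19 gene lists. In D146N minus WT, DIAPH1 differed by 5.75, SPECC1 by 5.05, AHNAK by 5, ANAPC2 by 4.90, AKAP12 by 4.48, PRKCA by 4.44, MACF1 by 4.24, CTNNB1 by 4.19, MT-RNR2 by 4.12 and DAAM1 by 4.10. In the other direction SCARNA16 differed by -17.76, RPPH1 by -14.70, SNHG20 by -11.43, RPL12P4 by -11.13, RPLP1 by -11.01, RPL12P16 by -10.89, RPL12 by -10.83, U2 by -10.53, SNORA53 by -10.50 and SNORA23 by -10.32. DIS3 differed by 2.04. The shares of 9 of 10 classes moved in opposite directions in every set, all but oxidative phosphorylation mRNAs (log2 ratio 0.05 in WT and 0.85 in D146N). The 9 had D146N minus WT log2 ratios of -2.86 for snRNA genes, 6.79 for snoRNA and scaRNA genes, -0.68 for 7SL, RNase P and MRP, Y and vault RNAs, 3.65 for mitochondrially encoded genes, 3.65 for mitochondrially encoded mRNAs, -2.67 for cytosolic ribosomal protein mRNAs, 2.21 for mitochondrial ribosomal protein mRNAs, 2.53 for histone mRNAs and 5.01 for proteasome mRNAs. These share differences were not tested beyond a permutation p of 0.1, the smallest possible. The rho of gene span with the fraction contrast differed by 0.251.

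The first pattern is this reversal, in which 99.3% of genes called in both genotypes had opposite signs. If fractions 3 and 4 had been exchanged with 7 and 8 in 1 genotype, or counted from opposite ends, libraries with opposite labels should be more alike, and they were: 226 and 668 genes (447 on average) differed 2-fold between opposite labels, against 6934.5 on average between the same labels. They were not the same, with 3275 genes called for D146N fractions 7 and 8 against WT 3 and 4 and 5524 for D146N 3 and 4 against WT 7 and 8, where DIAPH1 stood at 0.19 and 2.04, AHNAK at -0.04 and 1.67, SCARNA16 at -0.41 and -2.25, RPPH1 at -0.10 and 0.20 and DIS3 at -0.11 and 0.81. The large count between the same labels follows in good part from the reversal itself, so it is not separate support for an exchange. Scaling was argued against, because rank correlations, which no scaling changes, were higher between opposite labels by 0.349. Movement of RNA caused by D146N predicts the same opposite signs and could not be told apart from exchanged fractions with these data, so until the numbering is known no contrast within a fraction should be read as an effect of D146N.

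The second pattern is WT fraction 8 replicate 3, where 160 genes stood at least 4-fold above replicates 1 and 2, among them RPLP0 (3940 CPM), RACK1 (2830), GAPDH (956) and SRM (177), all 4 chosen after their values were seen. MT-RNR1 stood at 278 CPM there, against 0.191 and 0.243 in replicates 1 and 2 and at most 180 in any other library. Carry-over of RNA as in WT fractions 3 and 4 was argued against, since 35.6% of the raised genes stood above all 23 other libraries, and the others would need a median of 60.8% of such RNA where 475 genes far higher in WT fractions 3 and 4 allowed 1.53%. The limit of 20-fold for those 475 was kept after limits of 5, 10 and 50 had also been looked at, which gave 2.52%, 2.04% and 0.412%. Lower depth was argued against by a total 1.03 times that of the other replicates. No biological explanation was tested, and the cause could not be named.

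The third pattern is whether the counts of genes called could arise from any grouping of the libraries. For fractions 7 and 8 against 3 and 4, 1 of 100 splits (drawn from 462) reached the real count in WT and 1 of 100 in D146N, the real one, and the highest others were 10155 against 13980 and 6876 against 11387. These splits treated the libraries of a set as independent. For D146N against WT in fractions 3, 4, 7 and 8, in the sums, the interaction and the omnibus test, 1 of 10 splits reached the real count (9398, 9163, 12000, 12314, 5636, 14574 and 13520, with highest others of 1, 0, 0, 0, 1, 0 and 0), and 10 splits are too few. For fraction 4 against 3 and for 8 against 7, the real count was 0 (830 and 1215 genes at an unadjusted p under 0.05 with edgeR) and the highest other 1. As no split can call fewer than 0 genes, the 100 of 100 splits that were as large say nothing about chance.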

How the results depend on the processing

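The totals of counts left without small and mitochondrial RNAs, the leaving out of those that share their counts, the thinned sums and the check of replicate numbers were chosen after the result was seen, and the other tests before. Of 4146 alternative values for 208 named-gene results, 1810 kept direction and side of the threshold with all libraries and 2259 with 1 library or set left out, 52 became weaker, 4 stronger and 21 reversed. On library totals, which move the median of all genes, DDIT3 (-0.33), UBE2C (-0.11) and KMT2C (-2.39) reversed in the WT fraction contrast, PVT1 in the D146N contrast (0.61) and the interaction (0.61), and EXOSC1 (1.34), EXOSC4 (3.10), EXOSC8 (2.93) and C1D (1.97) in the interaction. On totals without small and mitochondrial RNAs EXOSC4 (1.37), EXOSC8 (1.19) and C1D (0.24), and KMT2C (-1.74) in the WT fraction contrast, reversed. In the sums CENPF (0.57 and 0.57), GOLGB1 (0.36 and 0.37), AKAP9 (0.17 and 0.18) and NCBP1 (0.05 and 0.06) reversed as the mean of the 4 contrasts and with limma voom. Library totals called 16746 genes in fraction 3, 16655 in fraction 4 and 17572 in the D146N fraction contrast, and totals without small and mitochondrial RNAs 15224 and 15095 in fractions 3 and 4. For fraction 8 against 7, no filter called 26, DESeq2 1 and edgeR without single libraries 0 to 2. In the sums limma voom called 3663. Leaving out single libraries or sets gave 8529 to 9654 genes in fraction 3, 8270 to 9473 in fraction 4, 11155 to 12135 in fraction 7, 11748 to 12225 in fraction 8, 4329 to 5723 in the sums, 13763 to 14305 in WT, 11064 to 12127 in D146N, 14679 to 15267 for the interaction, 13471 to 14087 for the omnibus test and 0 for fraction 4 against 3. With an estimated correlation 12 lists were called in fraction 3, 13 in fraction 4, 5 in the sums and 0 for 8 against 7. Fry called 32, 31, 29 and 30 in fractions 3, 4, 7 and 8, 26 in the sums, 29 in D146N, 31 in WT, 31 for the interaction and 0 for 8 against 7. The rho of gene span was -0.331 in WT and 0.253 in D146N at 10 CPM or more, -0.177 in WT set 3, 0.125 in D146N set 2 and 0.078 in D146N without small and mitochondrial RNAs. Apart from the library totals, the cause was not tested. Replicate numbers did not pair the libraries, as 6 of 24 were closest to their own number, and a block by number called 9305 genes in fraction 3 and 5456 in the sums.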

Other observations

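The test of hepatocyte RNA and the fold changes between opposite labels were chosen after the result was seen.

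ALB, AFP and APOB, transcripts typical of liver cells, were read in these kidney-derived cultures, at 119, 108 and 396 CPM in WT fraction 3 and 5.65, 4.98 and 18 CPM in D146N fraction 3. In D146N fraction 7 they stood at 137, 100 and 288 CPM. Hepatocytes or their RNA would bring their other abundant transcripts, and the bounds for that ratio (0.1 and 0.5) were set after levels had been seen. Over 22 other markers the highest median ratio to ALB was 0.0251, with APOA1 at 1.49 CPM, APOA2 at 1.4, TTR at 0.829 and HP at 0.0395 in WT fraction 3, which argues against hepatocytes with their usual proportions of transcripts. Other markers were higher there, with FGB at 21.2 CPM (0.178 of ALB, the highest ratio), FGA at 14.4, TF at 11.2, ITIH2 at 10.9, AMBP at 10.1, C3 at 9.88 and SERPINA1 at 9.74. The ratios were also low in WT fraction 7 (APOA1 0.332 and ALB 7.3 CPM). A cell type expressing ALB, AFP and APOB without the others was not tested.

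If opposite labels are set side by side, D146N fractions 7 and 8 against WT fractions 3 and 4 and D146N fractions 3 and 4 against WT fractions 7 and 8 shared 1768 called genes, of which 672 (38.0%) had the same sign. The fold changes of these 2 contrasts had an r of -0.017 across genes, which are not independent replicates. No gene rose 2-fold in both, and 3 fell, ENSG00000261135, LINC01967 and ERBIN-DT, all under 1 CPM and chosen after their values were seen.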
